A study of Mus musculus with 6 samples.

How the data were processed

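RNA in 6 samples from B16F10 tumors was profiled with a NanoString nCounter mouse cancer immunology panel, in which a barcoded reporter probe and a capture probe bind each transcript and barcodes are counted. Total RNA was extracted with a column kit, per the labels. The labels give 755 probe pairs, and the deposited table analysed here holds 750 genes with 1 column per sample. The deposited values are normalized signal, not raw counts, and every column is whole barcode counts multiplied by 1 factor per sample, as tested on the values. All values (100%) divided by their column's minimum came out whole within 0.001. How the authors computed the factor is not given in the sources used here. Control and reference probes were not used here, so the factor could not be recomputed. The lowest value in each column equals 1 count, so a value at 1 count may stand for 1 or fewer barcodes. Columns were matched to samples by name and number where the names allow it. The columns abbreviated PTX match no title and were taken as PROTEXI because they alone remained, so every PROTEXI value rests on that match. Replicate numbers were taken from the sample titles and groups from the titles and treatments in the labels, with 2 samples each in Vehicle, DC-Trp2 and PROTEXI.

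Values were tested as log2(value + 1) with limma (version 3.58.1, in R 4.3.3), with lmFit, eBayes and a trend of variance with mean, and with no further scaling. All 6 samples entered 1 fit with 3 group means and 3 residual degrees of freedom, from which the 3 comparisons between groups were taken. A gene was tested where at least 2 samples had a value of 20 or more, which kept 580 genes and left out 170. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The plan written before the data were examined named edgeR for raw counts and limma for normalized values, and the latter applied. The whole counts recovered from the normalized values were tested with edgeR (version 4.0.16, quasi-likelihood) and DESeq2 (version 1.42.0) with the deposited factors as alternatives. Gene lists were tested with fry, adjusted over 25 lists per comparison, for lists with at least 3 tested members. Camera with a preset correlation of 0.01 and with an estimated correlation was an alternative.

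The lists, fixed before the data were examined, were T cell markers, cytotoxicity genes, NK cell markers, Th1 and T helper genes, interferon-gamma response, type I interferon response, MHC class I presentation, MHC class II presentation, immune checkpoints, regulatory T cell genes, dendritic cell genes, macrophage and monocyte genes, neutrophil genes, B cell markers, mast cell and eosinophil genes, Th2 genes, Th17 genes, inflammatory cytokines, complement genes, cell cycle genes, melanocyte lineage genes, endothelial genes, fibroblast and matrix genes, lymphoid tissue genes, and epithelial and skin genes. Some lists share members. Of the 750 symbols, 736 were found in a table of mouse genes (assembly GRCm38.p6) used only for names, 8 of the 750 were updated by a synonym, and 14 were not found. Named genes followed a rule fixed before the data were examined. These were the 12 called genes with the largest rise and the 12 with the largest fall per comparison, filled up to 20 by the smallest unadjusted p where fewer than 20 were called. To these were added 12 fixed genes, Cd3e, Cd4, Cd8a, Gzmb, Prf1, Ifng, Foxp3, Pdcd1, Cd274, Cxcl9, H2-Ab1 and S100a8. For PROTEXI against DC-Trp2, up to 3 called members with the largest rise in each called list were added as examples, and this choice was made after their values were seen.

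The scripts were tested on simulated counts for 580 genes with 200 changed genes in each of 10 draws. The draws treated genes as independent, made rises and falls equally likely and added no shift of a whole sample. For PROTEXI against DC-Trp2, limma recovered 21.6% of genes changed by 1 on the log2 scale, 76.8% of those changed by 2 and 94.3% of those changed by 3. Of its calls 3.36% were false, a share that need not hold for the measured samples. The list test had little power. For PROTEXI against Vehicle, a T cell list shifted by 1 on the log2 scale was called by fry in 3 of 20 simulated draws, and unshifted draws called 0.05 lists on average. A gene at 20 counts carries a counting error of 22.4%, and such errors cover counting only.

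Alternatives planned before the data were examined were median centring, no filter, a filter over all 6 samples, DESeq2, edgeR, a pseudocount of 10, a fit of the compared groups alone, the replicate number as a block, leaving out each sample in turn, a threshold of 0.10 and both camera settings. Alternatives chosen after seeing the data were total-count scaling, TMM scaling with limma and with edgeR, leaving out genes at 1 count, a term for Vehicle 1 and PROTEXI 1, and a term for PROTEXI 2 and both DC-Trp2 samples. Figures were drawn with matplotlib.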

Results

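Immune gene expression was measured in 6 samples of tumors from B16F10, a mouse melanoma line grown under the skin of C57BL/6 mice of the same genetic background. The groups, of 2 samples each, were Vehicle, DC-Trp2 (a dendritic cell vaccine named for the melanocyte antigen Trp2) and PROTEXI (loaded with Trp2 and OVA323, a peptide name taken from the labels). Vaccines were given 3 and 10 days after tumor inoculation, and tumors were collected on day 13. The assay was a NanoString nCounter mouse cancer immunology panel, which counts fluorescent barcodes bound to each transcript without amplification. The table analysed holds 750 genes, of which 580 reached a normalized count of 20 in at least 2 samples and were tested. Recovered barcode counts per sample were 775718 and 798990 in Vehicle, 641788 and 507708 in DC-Trp2, and 770226 and 599739 in PROTEXI. The deposited values multiply these counts by 0.779 and 0.768 in Vehicle, 0.954 and 1.09 in DC-Trp2, and 1.06 and 1.52 in PROTEXI. The median normalized count over the 750 genes was 66.2 and 59.5 in Vehicle, 61.0 and 42.7 in DC-Trp2, and 116 and 171 in PROTEXI. The median absolute log2 difference between replicates over the tested genes was 0.21 in Vehicle, 0.33 in DC-Trp2 and 0.57 in PROTEXI, and the SD of that difference was 0.69, 0.54 and 1.02. Genes at 1 count numbered 36 and 12 in Vehicle, 4 and 4 in DC-Trp2, and 18 and 1 in PROTEXI. Nothing in the labels says that replicates are separate mice, so p-values measure only the spread between these samples, which may be technical. Fold changes are on the log2(normalized count + 1) scale, which understates the change of low genes.

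The first comparison asked how tumors treated with DC-Trp2 differed from Vehicle tumors. No gene passed the test, and the genes with the smallest p, among them Irf7, Fcgr1, Spp1 and Lgals3, mostly had lower values in DC-Trp2 tumors. Irf7, a transcription factor of the interferon response, measured 34.8 ± 7.42 in DC-Trp2 and 165 ± 0.0566 in Vehicle (SD, n = 2 each), a log2 fold change of -2.23 ± 0.32 (SE). Fcgr1, a high-affinity Fc receptor of myeloid cells, measured 52.9 ± 23.7 against 307 ± 13.0, a log2 fold change of -2.59 ± 0.49. Spp1 (osteopontin) and Lgals3 (galectin-3) had log2 fold changes of -1.51 ± 0.23 and -1.05 ± 0.17, and Stat2, a signal carrier of type I interferon, -1.27 ± 0.25. Cxcl9, a chemokine induced by interferon-gamma, had -3.05 ± 0.93, with 145 and 21.9 in DC-Trp2 against 421 and 541 in Vehicle.

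With limma, 0 of 580 genes were called between DC-Trp2 and Vehicle, with a smallest adjusted p of 0.230. At an unadjusted p under 0.05, 10 genes were higher and 60 lower, against 31 and 58 under total-count scaling, 40 and 58 under TMM scaling and 52 and 43 under median centring. edgeR on the recovered counts called 0 genes, and DESeq2 called 10, all lower in DC-Trp2. The median log2 fold change of the tested genes was -0.06, so the panel as a whole stood at the level of Vehicle. The remaining genes with the smallest p were Bst1 at -2.25, Fcgr4 at -2.27, Tlr9 at -1.73, Cxcl16 at -1.43, Ccl2 at -0.83, Lcp1 at -0.80, Ccl5 at -1.21, H2-T23 at -1.27, Jun at -0.84, Xcl1 at -1.46, Cfd at -2.85, Klrk1 at -1.37, Ccl12 at -1.27 and Slamf7 at -1.47. Maf, a transcription factor of T cells and macrophages, was the only gene among these 20 with a positive log2 fold change, 1.06 ± 0.28. Of the genes fixed in advance, Cd8a had a log2 fold change of -1.51 ± 0.63, Cd3e -1.45 ± 0.76, Gzmb -0.81 ± 0.74, Cd274 -0.63 ± 0.35, Prf1 -0.47 ± 0.38, H2-Ab1 -0.40 ± 0.57, S100a8 -0.16 ± 1.24, Pdcd1 -0.15 ± 0.62 and Cd4 0.25 ± 0.74. Centring each sample on its median turned the values of Pdcd1 and S100a8 to 0.08 each. Ifng and Foxp3 stayed under the filter and were not tested.

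No gene list was called between DC-Trp2 and Vehicle by fry, which tests whether the members of a list move one way. The interferon-gamma response list had a median log2 fold change of -1.22 with 16 of 19 tested members below 0, and fry gave an adjusted p of 0.496. The type I interferon list had a median of -1.09 with 20 of 22 members below 0, and 2 members, both lower, passed when adjusted over the list alone. MHC class I presentation had a median of -1.22 with 14 of 15 members below 0, and MHC class II presentation had a median of -1.06 with 9 of 9. The MHC class I and interferon-gamma lists share Nlrc5 and Psmb10, so they are not separate results. Relative to the Vehicle mean, the MHC class II median was -0.31 in DC-Trp2 1 and -1.52 in DC-Trp2 2. In the same order it was -0.86 and -1.66 for MHC class I and -0.67 and -1.72 for the interferon-gamma response. NK cell markers had a median of -0.79 and the smallest adjusted p from fry, 0.0926. That list passed under total-count scaling (adjusted p of 0.0434), under TMM scaling (0.0192) and with only these 2 groups in the fit (0.00882), but not under median centring (0.369). Camera with a preset correlation called the interferon-gamma, type I interferon, MHC class I and macrophage lists as lower than the other genes. None was called with an estimated correlation, where the smallest adjusted p = 0.815.

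**Figure D1:**
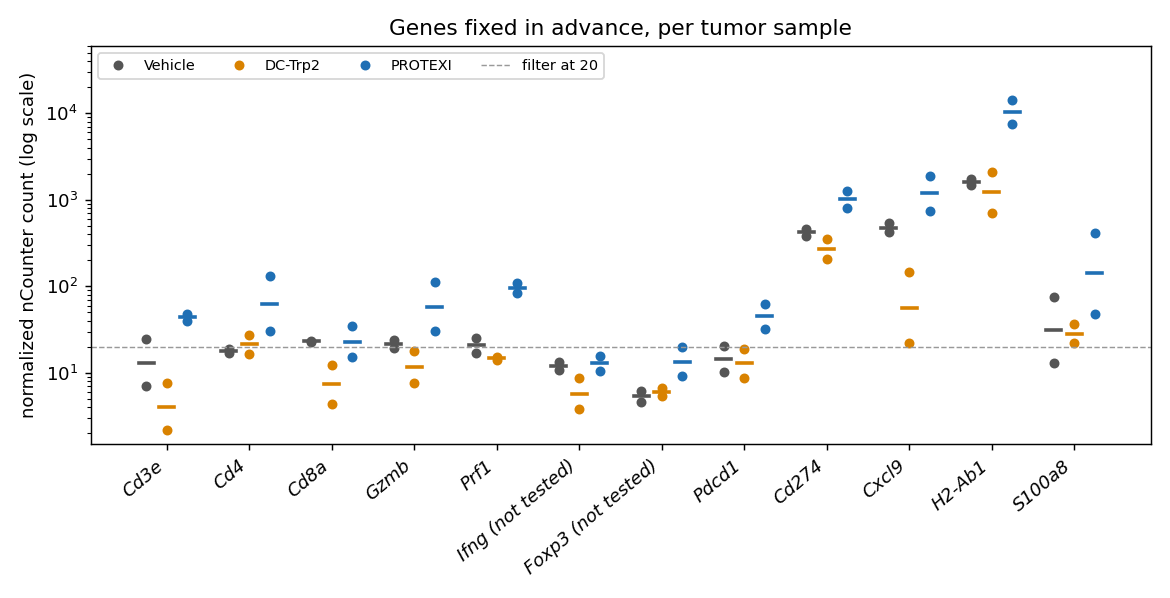
Normalized nCounter counts (vertical axis, log scale) of the 12 genes fixed in advance (horizontal axis), with 1 point per tumor sample, a bar at the geometric mean of the 2 samples of each group and a dashed line at the filter of 20. Prf1 lay at 109 and 84.9 in PROTEXI, above both Vehicle samples (17.1 and 25.3) and both DC-Trp2 samples (15.3 and 14.2), while Cd8a overlapped between PROTEXI and Vehicle.

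The second comparison asked how PROTEXI tumors differed from Vehicle tumors. No single gene passed the test, while the lists of T cell markers, NK cell markers and cytotoxicity genes rose as groups by fry. These 3 calls were lost under median centring and TMM scaling, and camera gave an adjusted p = 0.983 with an estimated correlation. Under total-count scaling cytotoxicity genes lost the call (fry adjusted p of 0.0701), while T cell markers (0.00719) and NK cell markers (0.0405) kept it. Prf1, the pore-forming protein of cytotoxic lymphocytes, measured 96.8 ± 16.8 in PROTEXI and 21.2 ± 5.80 in Vehicle (SD, n = 2 each), a log2 fold change of 2.15 ± 0.38. Ccl21a, a chemokine that draws T cells and dendritic cells into lymphoid tissue, measured 134 ± 57.6 against 8.89 ± 0.456, a log2 fold change of 3.70 ± 0.44. Il15ra, which presents interleukin-15 to lymphocytes, had a log2 fold change of 2.31 ± 0.38, and H2-T23, a nonclassical MHC class I gene, 1.73 ± 0.31.

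With limma, 0 of 580 genes were called between PROTEXI and Vehicle, with a smallest adjusted p of 0.0761. At an unadjusted p under 0.05, 236 genes were higher and 6 lower, against 104 and 63 under total-count scaling, 71 and 100 under TMM scaling and 48 and 120 under median centring. edgeR called 0 genes, and DESeq2 called 187, 184 of them higher in PROTEXI. The median log2 fold change of all tested genes was 0.80, and it was 0.31 under total-count scaling, 0.05 under TMM scaling and -0.22 under median centring. Other genes with the smallest p had log2 fold changes of 2.28 for Tnfrsf14, 1.63 for H2-M3, 1.85 for Itgb3, 2.55 for Sh2d1b1, 1.66 for Axl, 1.96 for Itgb2, 2.50 for Zap70, 1.17 for Il13ra1, 1.51 for Maf, 2.44 for Gbp2b, 2.07 for Marco, 2.47 for Klra2, 3.09 for Gzma, 2.20 for Cd48 and 2.31 for Entpd1. Of the genes fixed in advance, H2-Ab1, an MHC class II chain, had 2.68 ± 0.57, S100a8 2.12 ± 1.24, Cd4 1.78 ± 0.74, Cd3e 1.64 ± 0.76, Pdcd1 1.56 ± 0.62, Gzmb 1.40 ± 0.74, Cxcl9 1.32 ± 0.93 and Cd274 1.28 ± 0.35. Cd8a had -0.01 ± 0.63, with 34.8 and 15.2 in PROTEXI against a Vehicle mean of 23.2 ± 0.239. Leaving out PROTEXI 1 gave 255 calls, 241 of them higher, and a threshold of 0.10 gave 177.

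The T cell marker list rose in PROTEXI against Vehicle, with a median log2 fold change of 1.61 and 11 of 13 tested members above 0 (fry adjusted p of 0.00506, camera adjusted p = 0.983 with an estimated correlation). NK cell markers rose with a median of 1.33 and 8 of 8 members above 0 (adjusted p of 0.00506), and cytotoxicity genes with a median of 1.32 and 9 of 10 (adjusted p of 0.0303), each again with an adjusted p = 0.983 with an estimated correlation. These medians lay above the panel median by 0.82, 0.54 and 0.52. No member passed over all genes, while 6, 1 and 5 members of these lists were higher adjusted over the list alone. Among the lists that did not pass by fry, Th2 genes and MHC class II presentation each had a median of 2.09 (fry adjusted p of 0.114 and 0.0845). B cell markers had 1.61 (fry adjusted p of 0.0845) and macrophage and monocyte genes 1.40 (0.0845). Adjusted over the list alone, 4 of 6, 8 of 9, 0 of 6 and 9 of 22 members were higher in that order. The type I interferon list had the lowest median of the immune response lists, 0.28, and its direction turned under all 3 other scalings. The melanocyte lineage list, of 3 tested members (Kit, Mcam and S100b), had a median of -0.01 although fry gave it an upward direction. All 3 calls were also lost without the filter, without Vehicle 2, without PROTEXI 1 (where 3 other lists were called) and with a term for Vehicle 1 and PROTEXI 1.

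**Figure D2:**
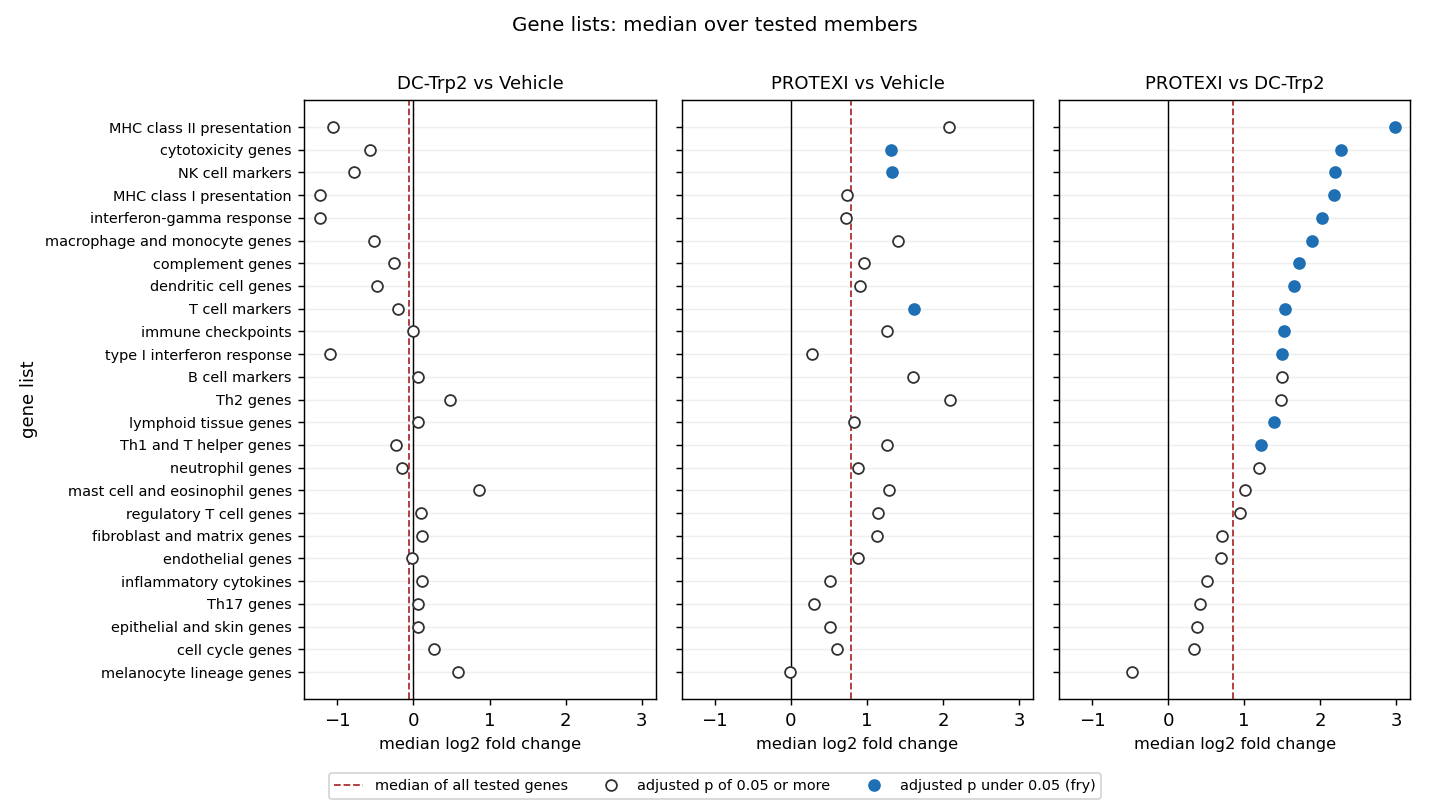
Median log2 fold change over the tested members of each of 25 gene lists (horizontal axis; lists on the vertical axis), in 1 panel per comparison, with filled points for lists called by fry and a dashed line at the median of all tested genes. The filled points number 0 for DC-Trp2 against Vehicle, 3 for PROTEXI against Vehicle and 13 for PROTEXI against DC-Trp2. In the last, MHC class II presentation had the highest median, 2.98. Camera with an estimated correlation called no list in any comparison.

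The third comparison set the vaccines against each other. MHC genes, genes induced by interferon-gamma and genes of NK cells, T cells and macrophages were among 112 genes higher in PROTEXI tumors than in DC-Trp2 tumors. These calls depend on the deposited scaling, as median centring called 19 genes higher and 72 lower, and total-count and TMM scaling called 0. Cxcl9 rose the most, 20.6-fold, with 1324 ± 817 in PROTEXI and 83.4 ± 87.0 in DC-Trp2 (SD, n = 2 each; log2 fold change 4.37 ± 0.93, limma adjusted p of 0.0326). Its log2 fold change was 5.70 without DC-Trp2 1 and 3.03 without DC-Trp2 2, where no gene passed, and the values were 3.96 and 2.39 for H2-Aa and 5.16 and 2.45 for Gbp5. The MHC class II chain H2-Aa rose 9.02-fold, from 1763 ± 1234 to 13828 ± 56.9 (3.17 ± 0.50, limma adjusted p of 0.0218). H2-T23 rose from 321 ± 120 to 2501 ± 381 (3.00 ± 0.31, limma adjusted p of 0.0212). Prf1 rose 6.17-fold, from 14.7 ± 0.727 to 96.8 ± 16.8 (2.63 ± 0.38, limma adjusted p of 0.0212).

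With limma, 112 of 580 genes were higher in PROTEXI than in DC-Trp2 and 0 were lower. Their fold changes ran from 1.81 to 20.6, with a median of 4.44. The largest rises after Cxcl9 were in Gbp5 and Gbp2b, guanylate-binding proteins of the interferon response (log2 fold changes of 3.81 ± 0.95 and 3.71 ± 0.47), and Psmb8, an immunoproteasome subunit (3.47 ± 0.81). Klra2, which encodes the receptor Ly49B known from myeloid cells, followed with 3.33 ± 0.48, H2-DMa, which helps load MHC class II, with 3.25 ± 0.59, and Il2rb, a receptor chain for interleukins 2 and 15, with 3.12 ± 0.60. Clec7a (dectin-1, a receptor of myeloid cells) had 3.09 ± 0.46, Cd3e, a chain of the T cell receptor complex, 3.09 ± 0.76, and H2-Ab1 3.09 ± 0.57. Cd3e measured only 7.63 and 2.19 in DC-Trp2, under the filter value of 20, so the size of its rise is uncertain. The same limit holds for Gbp2b (14.3 and 6.57) and Prf1 (15.3 and 14.2), and for Gbp5 in DC-Trp2 2 (62.9 and 8.76). The DC-Trp2 samples also differed from each other in Psmb8 (661 and 160), H2-DMa (261 and 79.9) and H2-Ab1 (2103 and 709). Cd274, which encodes PD-L1, rose by 1.91 ± 0.35. Gzmb (2.21 ± 0.74), Pdcd1 (1.72 ± 0.62), Cd4 (1.53 ± 0.74), S100a8 (2.27 ± 1.24) and Cd8a (2.83-fold) did not pass, with limma adjusted p from 0.0838 to 0.208.

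By gene list, fry called 13 of 25 lists as higher in PROTEXI than in DC-Trp2 and none as lower. Some of these lists share members, so the 13 calls are not independent. Examples are Nlrc5 and Psmb10 (interferon-gamma and MHC class I) and C1qa and C1qb (macrophage and complement). Camera called none, with a smallest adjusted p = 0.784 with an estimated correlation. At a preset correlation it called 3 of them as higher than the other genes (interferon-gamma response, MHC class II presentation, macrophage and monocyte genes) and the melanocyte list as lower. The tested members of the melanocyte list were only Kit, Mcam and S100b. Kit measured 1.06 and 63.7 in PROTEXI against 33.4 and 62.4 in DC-Trp2. The low PROTEXI 1 value is a single barcode count, so the melanocyte call may rest on that probe. Of the 13 calls by fry, 2 stayed under total-count scaling (T cell markers and NK cell markers), 1 under TMM scaling (NK cell markers) and 0 under median centring. In MHC class II presentation 8 of 9 tested members rose (9 adjusted over the list alone), with a median log2 fold change of 2.98. In MHC class I presentation 7 of 15 rose (12 adjusted over the list alone), among them Psmb8, H2-T23 and the class I regulator Nlrc5 (2.85 ± 0.67), with a list median of 2.19. In the interferon-gamma response 9 of 19 rose (14 adjusted over the list alone; median 2.02), led by Cxcl9, Gbp5 and Gbp2b. In the type I interferon response 6 of 22 rose (12 adjusted over the list alone; 21 of 22 above 0), led by Irf7 (2.23 ± 0.32), Oas2 (2.21 ± 0.37) and Usp18 (1.86 ± 0.46). Irf7 stood at the Vehicle level in PROTEXI (166 ± 26.6 against 165 ± 0.0566) and below it in DC-Trp2.

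**Figure D3:**
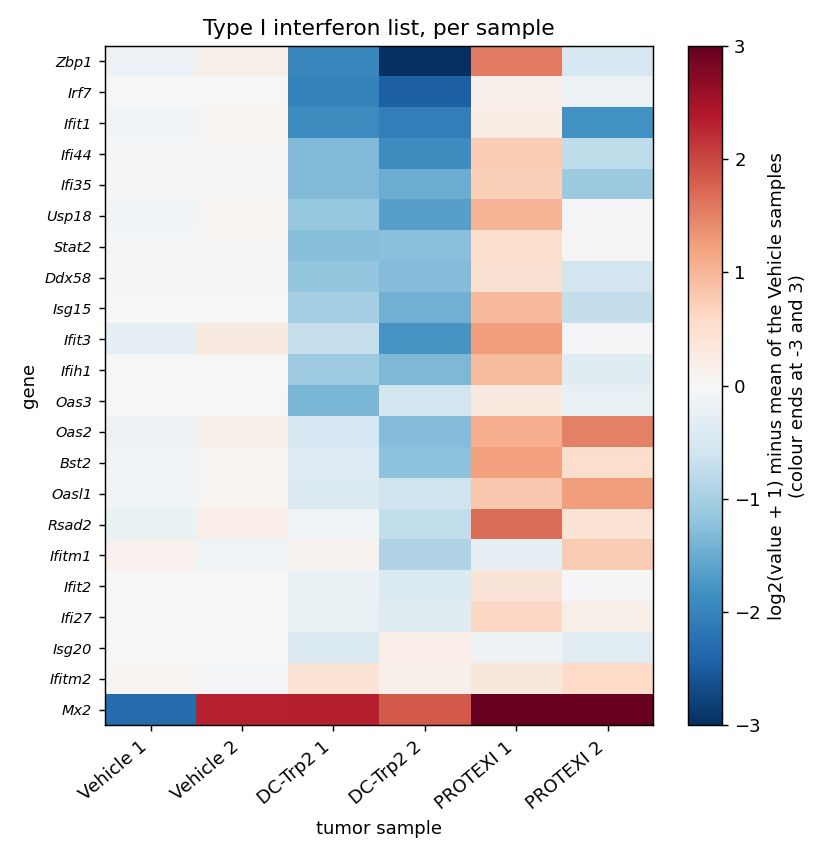
Log2(normalized count + 1) of the 22 tested type I interferon genes (rows) in the 6 tumor samples (columns), as the difference from the mean of the Vehicle samples (colour scale, log2). Most genes were lower in both DC-Trp2 samples, with a list median of -1.09, and the PROTEXI samples differed, with a median of 0.74 in PROTEXI 1 and -0.05 in PROTEXI 2.

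Lymphocyte lists were among the 13 called by fry, and camera called none of them (smallest adjusted p = 0.784 with an estimated correlation). In NK cell markers 4 of 8 members rose (6 adjusted over the list alone; median 2.19), among them Klra2, known from myeloid cells, Ncr1 (2.60 ± 0.55) and Klrc1 (2.15 ± 0.49). In cytotoxicity genes 4 of 10 rose (6 adjusted over the list alone; median 2.27), led by Prf1, Klrk1 (2.61 ± 0.36) and Ctsw (2.44 ± 0.47). In T cell markers 7 of 13 rose (7 adjusted over the list alone, median 1.54), among them Cd3e, Zap70 (2.14 ± 0.46) and Cd3d (2.02 ± 0.47). The value of Cd3e rests on 7.63 and 2.19 in DC-Trp2, under the filter value of 20. Ncr1 (10.5 and 5.47) and Zap70 (18.1 and 14.2) were also under that value in DC-Trp2. Th1 and T helper genes had 2 of 9 (6 adjusted over the list alone; median 1.22), among them Cxcr6 (2.18 ± 0.41). Lymphoid tissue genes had 1 of 7 (4 adjusted over the list alone; median 1.39), Ccl21a (2.89 ± 0.44). Immune checkpoints had 3 of 12 (9 adjusted over the list alone; median 1.53), Cd200r1 (2.28 ± 0.57), Tnfrsf14 (2.21 ± 0.41) and Cd274.

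Among myeloid lists, called by fry (camera smallest adjusted p = 0.784 with an estimated correlation), macrophage and monocyte genes had 10 of 22 members higher (17 adjusted over the list alone; median 1.90), led by Ly86 (2.95 ± 0.56), Marco (2.51 ± 0.40) and Emr1 (2.29 ± 0.49), the older symbol of the macrophage marker F4/80. Dendritic cell genes had 3 of 14 (8 adjusted over the list alone; median 1.66), Cd86 (2.04 ± 0.49), Cd40 (1.94 ± 0.47) and Cd1d1 (1.72 ± 0.40). Complement genes had 6 of 17 (10 adjusted over the list alone; median 1.72), led by Cfd (2.98 ± 0.74), C1qa (2.07 ± 0.41) and C1qb (2.02 ± 0.37). In DC-Trp2, Cfd measured 26.7 and 9.85 and Marco 14.3 and 9.85, so the sizes of their rises are uncertain. The fry adjusted p of the 13 lists ran from 0.00257 for T cell markers and NK cell markers to 0.0352 for dendritic cell genes. The other lists did not pass, with adjusted p from 0.0627 to 0.427. All 6 tested B cell markers had values above 0, and the medians of the others were 1.48 for Th2 genes, 1.20 for neutrophil genes, 1.01 for mast cell and eosinophil genes, 0.94 for regulatory T cell genes, 0.71 for fibroblast and matrix genes, 0.69 for endothelial genes, 0.51 for inflammatory cytokines, 0.42 for Th17 genes, 0.38 for epithelial and skin genes, 0.35 for cell cycle genes and -0.48 for melanocyte lineage genes.

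The panel as a whole also stood higher in PROTEXI, with a median log2 fold change of 0.86 against DC-Trp2 that was 0.30 under total-count scaling, 0.05 under TMM scaling and -0.39 under median centring. The direction of the 112 called genes held in 110 genes under median centring and in all under total-count and TMM scaling, but the calls did not. These genes were picked for their rise on the deposited scaling, so the kept direction is no independent support. Of the 112 genes, 19 were called under median centring. DESeq2 called 213 genes, all higher. The immune checkpoint list turned its direction under median centring by fry, and Th1 and T helper genes had a median of -0.02 there. No gene was called without Vehicle 1, without Vehicle 2 or without DC-Trp2 2, and 61, 268 and 90 genes were called without DC-Trp2 1, PROTEXI 1 and PROTEXI 2. Leaving out a Vehicle sample did not change the fold changes between the vaccines (panel median still 0.86), only the estimated spread. The probes of Kit and Myd88 stood at 1 count in Vehicle 1 and PROTEXI 1 and at 35 or more in the other samples. With a term for Vehicle 1 and PROTEXI 1 no gene was called. Within those 2 samples the panel median of PROTEXI 1 minus Vehicle 1 was 0.54. Outside them that of PROTEXI 2 minus Vehicle 2 was 0.89 and that of PROTEXI 2 minus the DC-Trp2 mean 1.07.

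Relative to Vehicle, 97 of the 112 called genes had a higher mean in PROTEXI and a lower mean in DC-Trp2, 11 were higher in both and 4 lower in both. Under median centring, total-count scaling and TMM scaling the count of 97 was 61, 86 and 77. The median log2 fold change of the 112 genes against Vehicle was 1.31 in PROTEXI and -0.81 in DC-Trp2. Across the 580 genes, which are not independent replicates, the fold changes of both vaccines against Vehicle correlated with Pearson's r of 0.29. Simulated noise without any change, drawn for all 6 samples and independently for each gene, gave 0.50 (95% range 0.37 to 0.61). A shared Vehicle mean alone produces such a value, and the draws lack the correlation between genes. The covariance was 0.186 against a simulated 0.126. With Vehicle 1 used for DC-Trp2 and Vehicle 2 for PROTEXI, r was 0.04, and the other way round it was 0.15, each with 1 control sample.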

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

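The tests of explanations in this part were all chosen after the results were seen. Of the 112 genes called between PROTEXI and DC-Trp2, 97 had means above Vehicle in PROTEXI and below Vehicle in DC-Trp2. The difference between the vaccines was tested, but neither vaccine's own difference from Vehicle passed for any gene with limma, and the count of 97 was 61 under median centring. Genes picked for a difference between the vaccines favour a Vehicle value in between, so the count by itself does not show opposite movement.

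PROTEXI tumors stood above Vehicle over most of the panel, with a median log2 fold change of 0.80. The deposited scaling factor as the whole cause is argued against, because 1 factor moves all genes alike, while genes of 50 to 200 counts rose above genes of over 1000 counts by 0.72 (95% bootstrap interval over genes 0.58 to 1.01). Background was taken as the median count of the genes not tested, which was 6 to 10 counts per sample. Subtracting so few counts could hardly move genes of 50 to 200 counts, whose median was 1.07 (0.97 to 1.32) after and 1.07 before. This shows only that a background of that size does not account for the rise of these genes. Background multiplied by a larger factor was not tested in genes under 50 counts and stays open there. More leukocyte transcripts in the tumors stay open, as 72 marker genes of leukocytes had a median of 1.25 against 0.73 for the other genes, but camera with an estimated correlation gave a p of 0.575. The other genes of this immune panel include MHC class II presentation and most cytotoxicity genes, so the comparison can miss such a rise. How far the factor lifts the whole panel was not tested and stays open.

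Mx2, Ccrl2, Kit, Myd88, Creb5 and Tnfaip3 stood at 1 count in Vehicle 1, Kit and Myd88 also in PROTEXI 1, and at 12 or more in the other samples. Counting error is argued against, because the largest Poisson probability of so low a count was 7.81e-11. A change of the interferon program in Vehicle 1 is argued against for Mx2, since the other type I interferon genes differed from Vehicle 2 by a median log2 of -0.0665. Genes at 1 count numbered 36 in Vehicle 1 and 18 in PROTEXI 1, with 17 shared, against 12, 4, 4 and 1 in the other samples, and a difference between runs was not tested and stays open. Leaving out genes at 1 count called 123 genes between PROTEXI and DC-Trp2, including all 112.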

How the results depend on the processing

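Total-count scaling, TMM scaling with limma and with edgeR, leaving out genes at 1 count, and a term for either of 2 sample groupings were chosen after the data were seen, and the other settings were planned. Scaling by housekeeping genes or positive controls and subtraction of negative controls were not run, since no such probes were used here. Total-count scaling, planned for raw counts, was applied to the normalized values. Where a group is left with 1 sample, that sample is assumed to vary like the others, and the cause was not tested for any change below. For DC-Trp2 against Vehicle, DESeq2 called 10 genes, only the compared groups in the fit 5, and leaving out single samples 0 to 5. Lists called there numbered 1 under total-count scaling, 1 under TMM scaling, 1 with only the compared groups and 4 with camera at a preset correlation. For PROTEXI against Vehicle, DESeq2 called 187 genes, a threshold of 0.10 called 177, and leaving out single samples 0 to 255. The count of called lists, 3, became 0 under median centring, TMM scaling, no filter, the replicate block, the term for Vehicle 1 and PROTEXI 1, and both camera settings, 1 with only the compared groups and 1 with the term for PROTEXI 2 and both DC-Trp2 samples, and 0 to 3 without single samples, where each removal lost 2 or 3 of the original calls and the 3 without PROTEXI 1 are other lists. A filter over all 6 samples also left 0, as T cell markers lost the call (adjusted p of 0.0971) and the other lists had too few tested members. Total-count scaling lost 1 of the 3 calls, that of cytotoxicity genes (fry adjusted p of 0.0701). For PROTEXI against DC-Trp2, 112 calls became 0 under total-count scaling, TMM scaling with limma or edgeR, only the compared groups, the replicate block and the term for Vehicle 1 and PROTEXI 1. They became 71 under the filter over all 6 samples, 213 with DESeq2, 219 at a threshold of 0.10, and 0 to 268 without single samples. The term for PROTEXI 2 and both DC-Trp2 samples gave 263, but that grouping was read from the expression values, so it is no independent evidence. Calls were 107 without the filter, 108 with edgeR and 119 with a pseudocount of 10. The count of called lists, 13, became 0 under median centring, 2 under total-count scaling, 1 under TMM scaling, 2 with only the compared groups, 3 with the replicate block, 2 with the term for Vehicle 1 and PROTEXI 1, 4 and 0 with camera at a preset and an estimated correlation, and 2 to 11 without single samples. The 4 include the melanocyte list, not among the 13, and the 11 without PROTEXI 1 include 4 new lists, with 6 lost. Deviations of samples with the same replicate number correlated over genes at 0.0601, -0.0491 and 0.0211, which gave no sign of pairing by number. Such correlations cannot exclude a run shared by some samples, such as Vehicle 1 and PROTEXI 1. Under median centring, 110 of the 112 genes called between PROTEXI and DC-Trp2 kept their direction, but they were picked for their rise on the deposited scaling. The median of Th1 and T helper genes became -0.02 under that centring, and fry gave immune checkpoints as down with a median still at 0.28. Directions also turned in values that did not pass. In DC-Trp2 against Vehicle, Cd4 became -0.228 with the term for Vehicle 1 and PROTEXI 1. With the term for PROTEXI 2 and both DC-Trp2 samples, Cd4 became -1.80, Gzmb 1.04, Pdcd1 0.818 and Cd274 0.0242. Median centring gave Pdcd1 0.0804 and S100a8 0.0754. Without single samples, Cd4 ran from -0.108 to 0.610, Pdcd1 from -0.673 to 0.368 (0.330 without Vehicle 2), H2-Ab1 from -1.19 to 0.379, and S100a8 from -1.39 to 1.07 (0.212 without DC-Trp2 2). In PROTEXI against Vehicle, Cd8a became 0.121 with DESeq2, 0.129 with edgeR, 0.0163 with a pseudocount of 10, 0.00144 without Vehicle 1 and -0.583 to 0.566 over all single samples left out, and 0.566 with the term for PROTEXI 2 and both DC-Trp2 samples. Lists that had not passed also turned direction, and the choice to count these instead of printing each was made after seeing how many there were. Under median centring, total-count scaling and TMM scaling these were 6, 3 and 3 lists for DC-Trp2 against Vehicle, 12, 3 and 9 for PROTEXI against Vehicle, and 9, 3 and 6 for PROTEXI against DC-Trp2. Under the other settings tested with fry they were 0 to 9, 0 to 1 and 0 to 1. Camera compares a list with the other genes, so its directions were not counted. The correlation of both vaccines' fold changes was 0.0387 and 0.146 with the Vehicle samples split. A gene at 20 counts carries a counting error of 22.4%, which limits low genes such as Cd8a.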

Other observations

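The values set beside explanations in this part were all chosen after the results were seen. The PROTEXI samples differed from each other more than the samples of the other groups did, with 166 of 580 genes over 2-fold apart. Of these, 135 were higher in PROTEXI 2 and 31 higher in PROTEXI 1. These counts are not corrected for a shift of the whole panel, as genes outside the type I interferon list stood higher in PROTEXI 2 by a median log2 of 0.38. The genes named in this part were chosen after their values were seen. Chil3, a marker of alternatively activated macrophages, measured 2124 in PROTEXI 2 and 41.2 in PROTEXI 1. The complement gene C3 measured 5913 against 528, the collagen gene Col1a1 12587 against 2314, Lyz2 (lysozyme of myeloid cells) 43925 against 8911, Mrc1 (the macrophage mannose receptor) 1795 against 386, and Lif 296 against 10.6. Psmb9 measured 664 in PROTEXI 2 against 3472 in PROTEXI 1, and Irgm2 515 against 2487.

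Type I interferon genes divided the samples differently from most of the panel, which was noticed while looking through all 10 ways of parting the 6 samples 3 against 3. Of 22 tested members, 10 lay higher in both Vehicle samples and PROTEXI 1 than in both DC-Trp2 samples and PROTEXI 2, against 41 of 558 other genes and a chance share of 5%. That share is for this direction only. Counted in either direction, this parting separated 10 of the 22 and 84 genes in all. On the same count another way of parting the samples separated 7 of the 22. Others separated more genes in all, up to 191, so the pattern is a hypothesis. The list's median log2 difference, PROTEXI 2 minus PROTEXI 1, less that of the other genes, was -0.99 (95% bootstrap interval -1.69 to -0.72). Vehicle 2 minus Vehicle 1 was 0.0665 for this list without Mx2. Both values restate the pattern, which was picked from these same samples, so neither is a separate test of an explanation. The scaling of PROTEXI 2 and a run of Vehicle 1 and PROTEXI 1 without Vehicle 2 were not tested otherwise. A run that also held Vehicle 2 was not tested and stays open. Genes at 1 count numbered 36, 12 and 18 in Vehicle 1, Vehicle 2 and PROTEXI 1 against 4, 4 and 1 in the others.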
